A study of Mus musculus with 358 samples.

How the data were processed

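The series holds 358 arrays of brain, kidney and liver total RNA from mice of the strains labelled B6, FVB and 129, each hybridised against Universal Mouse Reference RNA (Stratagene) on 2-colour slides, with the tissue in Cy3 on some arrays and in Cy5 on the others. Groups were read from the labels alone as strain, age, tissue and sex, which gives 30 groups, each with 3 biological replicates and 10 to 12 arrays. The deposited values are linear ratios, 1 per probe on each array, and the labels do not state their direction. Outside FVB kidney M3, arrays of one sample with opposite dyes correlated positively, so the ratio was read as already turned for the dye. Lists of neuron, kidney tubule and hepatocyte genes lay below 1 in their own tissue, so it was read as reference over tissue and inverted. Ratios of 0 (6130 values) were set to missing, and log2 values were centred on the median of each array, since array medians of the deposited ratio ran from 0.326 to 2.57, with a median of 0.695 for Cy3 tissue and 1.35 for Cy5 tissue. No background or spot quality is given in the sources used here, so no array carries a measure of depth beyond the number of probes with a value, 8766 to 11980.

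In 6 arrays the label lines contradict each other and these arrays were not used: 3 state liver as the channel source under a 129 brain title, and 3 state dyes that differ between lines. Of the remaining 352 arrays (179 with tissue in Cy3, 173 in Cy5), 3 belong to FVB liver F2 at 1 week, which kept 1 dye only and was left out. The comparisons rest on 349 arrays (176 and 173) of 89 of 90 biological samples, and the array-level alternative on 352. Arrays of a sample with the same dye correlated across probes at a median of 0.955 (lowest 0.464), and arrays of opposite dyes at 0.697 (lowest -0.334). The 4 arrays below 0, all of FVB kidney M3, were kept, since none correlated below 0 with the mean of the other arrays of the sample. Among arrays of different samples with the same dye, the lowest correlation was -0.259 over 15840 pairs of Cy3 arrays and -0.322 over 14793 pairs of Cy5 arrays, the latter between a 129 liver and a B6 kidney, so directions were kept as stated. The values of each biological sample were averaged within dye and then over both dyes. A sample without a value in either dye counted as missing for that probe, and n counts biological samples. Probes were tested when at least 2 samples of each group had a value.

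Of 12304 probes, 8681 map to 1 gene symbol, 510 to several and 3113 to none, and 6471 genes are covered. Comparisons used limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with a fit of all group means per tissue, or of all tissues together for tissue contrasts. Variances were moderated, p-values were two-sided and adjusted after Benjamini and Hochberg over all probes of a contrast, and a probe was called at an adjusted p below 0.05. The contrasts were the 3 pairs of tissues and the 3 pairs of strains at 1 week, 8 weeks minus 1 week and 6 months minus 8 weeks in B6, female minus male at 1 week and in adult B6, and the difference between these sex effects in B6. Counts in all 3 tissues are probes called with one sign in each. Plots were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

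Gene lists for 29 cell types, pathways and sex- or strain-related groups were fixed before the data were examined. The 27 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Each list's genes were also adjusted over the list alone. The rule for naming genes was fixed with them. It took 1 probe per gene, the one with most values, and called genes only. For each tissue it took the 10 genes with the largest smaller fold over the other tissues that were higher in all 3 strains. For each strain pair it took up to 4 highest and 4 lowest among those called with one sign in all 3 tissues and, per tissue, the 2 highest and 2 lowest with one sign in both sexes. Per tissue it took the 10 highest and 10 lowest between 1 and 8 weeks and 3 of each between 8 weeks and 6 months, with one sign in both sexes. For sex it took 3 of each at 1 week with one sign in all 3 strains, 8 of each in adults with one sign at both ages, and 2 of each for the difference between ages. Members of the fixed lists were named as well. The alternatives chosen beforehand were scaling of arrays to one spread, all 358 arrays, Cy3 or Cy5 arrays alone, replicate number as a block, no probe filter, each sample left out, only the groups of the contrast in the fit, an array-level fit with a dye term and duplicateCorrelation, and the estimated correlation for lists. Chosen after seeing the data were the array set as a block, matched parts of the slide, no centring, centring by slide part, leaving out FVB kidney M3 or copied values, male kidneys alone, and 2 replacements of the 1-week B6 samples in sex contrasts.

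Replicate numbers were tested as pairs by correlating residuals of equal numbers between groups. All 3 numbers correlated above 0.1 in 14 of 30 pairs of tissues, 7 of 15 pairs of sexes, 0 of 18 pairs of strains and 0 of 12 pairs of ages, and numbers were not used as pairs except in the alternative named. Array sets were read from which probes carry values, and the 2 slide parts from correlations of tissue differences between sets. The procedure was tested on simulated data with differences added to 50 probes of each size. Of probes with a log2 fold of 1, 82% were recovered for B6 against FVB in kidney, 80% for 8 weeks against 1 week in liver and 70% for adult sex in kidney. Of those with a log2 fold of 0.5, the shares were 24%, 30% and 14%. The score of sex-linked genes was compared by exact permutation of the sex labels within each tissue, two-sided, in 5 groups (p adjusted after Benjamini and Hochberg over the 5), and again with tissues averaged per replicate number and sexes exchanged over the 6 numbers of a group, chosen after the values were seen. Groups of samples were redrawn 100 times per comparison, the real grouping included.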

Results

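Gene expression was measured in brain, kidney and liver of mice of 3 strains, labelled B6, FVB and 129, on 2-colour arrays that set the RNA of 1 tissue sample against a common mouse reference RNA. The labels divide 358 arrays into 30 groups by strain, age, tissue and sex. FVB and 129 were sampled at 1 week, and B6 at 1 week, 8 weeks and 6 months, each in 3 tissues and both sexes. Every group has 3 biological replicates by the labels, on 10 to 12 arrays with the dyes exchanged. After 6 arrays with contradictory labels and 3 of a sample measured with 1 dye only were left out, 349 arrays of 89 biological samples entered the comparisons, with values at 8766 to 11980 probes. The number of arrays limits the precision, and the labels do not say whether replicates came from separate animals, so every p-value measures only the spread between samples. The labels state no question, so the comparisons below follow the groups: tissue, strain, age and sex. Levels are log2 of tissue over reference RNA, differences are log2 folds ± standard error, levels of groups are given ± SD, and n counts biological samples.

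The 3 tissues were first compared in 1-week mice of all 3 strains (brain n = 18, kidney n = 18, liver n = 17). The genes highest in each tissue included genes of its main cell types. Brain was highest for Crmp1 and Gap43, which act in axon growth, by 5.46 ± 0.18 and 4.57 ± 0.15 over the next tissue. Kidney was highest for Napsa, an aspartic protease of the proximal tubule, by 4.99 ± 0.19, for the cystine transporter subunit Slc7a9 by 4.15 ± 0.14, and for Slc12a1, the salt transporter of the thick ascending limb, by 3.67 ± 0.25. Liver was highest for Bhmt and Mat1a, enzymes of methionine metabolism, by 5.74 ± 0.25 and 5.33 ± 0.20, and for the haem-binding plasma protein Hpx by 5.17 ± 0.22. In limma, 3953 of 9746 probes differed between brain and kidney (1966 higher in brain, 1987 lower), 5670 of 9744 between brain and liver (2445 higher in brain, 3225 lower) and 3779 of 9744 between kidney and liver (1833 higher in kidney, 1946 lower). Of 6393 genes, 1212 were higher in brain than in both other tissues, 580 in kidney and 1056 in liver. The 10 genes named for brain also held Camk2n2, Camk2b, Meg3, Ctnna2, Nsg1, Stmn3, Sez6 and Brd2, with margins of 4.31 to 5.17. Those for kidney also held Klk1, Cdh16, the anti-ageing hormone Kl (3.71 ± 0.18), Mep1a, Psme3, Rfwd3 and Hoxd9, with margins of 3.13 to 4.67. Those for liver also held Elovl1, Itih4, Cyp1a2, Pzp, F12, Fgg and Asgr1, with margins of 4.97 to 5.77. Samples overlapped between tissues for Camk2b, Stmn3, Hoxd9 and Itih4.

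The neuron, kidney tubule and hepatocyte lists served to fix the direction of the deposited ratio, so their direction in the tissue contrasts is not a test. Of 16 neuron genes, 15 were higher in brain than in kidney and 15 higher than in liver, with the migration protein Dcx at 3.71 ± 0.15 and Map2 at 3.33 ± 0.14 over kidney. Nrgn, a synaptic protein of mature forebrain neurons, differed by 0.04 and was not called. Of 17 tubule genes, 15 were lower in brain than in kidney, with Umod at -3.34 ± 0.28 and the endocytic receptor Lrp2 at -2.97 ± 0.16, while Calb1 was higher in brain by 1.59 ± 0.12. Of 25 hepatocyte genes, 22 were lower in brain and 22 lower in kidney than in liver, with adjusted p = 0.00144 and 2.09e-05 with an estimated correlation, and Apob was higher in brain by 1.81 ± 0.15. The complement and coagulation list had 19 of 20 genes below liver in brain and 19 in kidney (adjusted p = 0.000348 and 9.03e-06 with an estimated correlation), among them Hc, the gene of complement C5, at -5.07 ± 0.16 in brain. The xenobiotic and P450 list had 20 of 24 genes below liver in brain (21 when adjusted over the list alone) and 18 in kidney, with adjusted p = 0.00218 and 0.00261 with an estimated correlation; Cyp3a11, a broad drug oxidase, lay at -4.33 ± 0.13 in brain. Liver also carried more of the leukocyte list, 20 of 23 genes over brain and 20 over kidney (adjusted p = 0.000727 and 9.03e-06 with an estimated correlation), including lysozyme Lyz2 (-3.35 ± 0.14 in brain) and the neutrophil protein S100a9 (-3.18 ± 0.15 in brain). Of 10 erythroid genes, 8 were higher in liver than in brain and 8 higher than in kidney (adjusted p = 0.0407 and 0.00681 with an estimated correlation), among them the Rh antigen Rhd at -1.16 ± 0.13 in brain. The male-higher in adult liver list had 4 of 5 genes lower in kidney than in liver (adjusted p = 0.039 with an estimated correlation) and 3 of 5 lower in brain (0.137).

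Extracellular matrix genes were lower in brain than in kidney for 14 of 19 members, 16 when adjusted over the list alone (adjusted p = 0.0221 with an estimated correlation), among them Tgfbi at -3.16 ± 0.16 and the basement membrane collagen Col4a2 at -2.77 ± 0.16. Kidney exceeded liver for 10 of the 19, with Col4a2 at 2.38 ± 0.16 (adjusted p = 0.058 with an estimated correlation). Cholesterol synthesis genes were higher in brain than in kidney for 6 of 8 members, including Fdft1 at 1.62 ± 0.10 and Hmgcs1 at 1.42 ± 0.17 (adjusted p = 0.133 with an estimated correlation). Among 10 astrocyte genes, 5 were higher in brain than in kidney and 2 lower, with Fabp7 of radial glia at 2.73 ± 0.11 and S100b at 2.34 ± 0.18 (adjusted p = 0.252 with an estimated correlation). Among 9 myelin and oligodendrocyte genes, 5 were higher in brain than in kidney and 2 lower, with Mbp at 3.00 ± 0.23 and Cnp at 2.73 ± 0.15, and camera did not call the list. Fatty acid oxidation genes were lower in brain than in kidney for 9 of 13, including Acaa2 at -2.01 and Acads at -1.85 (adjusted p = 0.213 with an estimated correlation). Cell cycle genes were lower in brain for 13 of 28 against kidney (adjusted p = 0.369 with an estimated correlation) and 19 of 28 against liver (0.255). Adipose genes were lower in brain than in kidney for 4 of 5 members, with Ucp1 of brown fat at -2.84 ± 0.21, and 3 of 5 higher in kidney than in liver (adjusted p = 0.0995 with an estimated correlation). Of the strain-variable list 5 of 7 and of the male-higher in adult kidney list 4 of 8 were lower in brain than in kidney (adjusted p = 0.184 for both with an estimated correlation). Of the female-higher in adult liver list 5 of 6 were lower in brain than in liver (0.117). Of the oxidative phosphorylation list 8 of 19 and of the ribosomal protein list 8 of 13 were lower in brain than in kidney, and camera called neither. The nephron progenitor and podocyte, skeletal muscle, adrenal, exocrine pancreas and immediate early and stress lists passed camera in none of the 3 contrasts. Osr1 (0.88 ± 0.12), the muscle creatine kinase Ckm (0.66), Hsd3b1 (-1.49), Cela1 (-2.17) and Fos (1.23 ± 0.35) were members called between brain and kidney. With the array set as a block, described below, 4039, 5702 and 3900 probes were called, and within sets A, B and C 87.3% to 99.0% of the probes called over all sets and tested there had the sign of the pooled fold.

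Several 1-week kidney samples carried liver transcripts. Over 66 genes at least 8-fold higher in liver than in kidney, the median level reached 2.89%, 2.81% and 4.07% of the liver level in the 3 samples labelled B6 female, against 0.059%, 0.0348% and -0.0983% in the 3 labelled male. Sample F1 of 129 reached 8.11%, F3 2.49% and M3 2.19%, and FVB F3 1.87%, while the other 8 kidneys of these strains lay between -0.311% and 0.596%. Albumin, Alb, stood at 4.39 ± 0.88 (SD, n = 3) in the B6 female kidneys and 0.22 ± 0.48 (SD, n = 3) in the male, against 5.82 in 1-week liver. These samples enter each contrast of 1-week kidney. From male samples alone 3124 probes were called between brain and kidney and 2538 between kidney and liver. The strain and age counts below have a count from male kidneys beside them, and 129 M3 remains among the males.

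**Figure D1:**
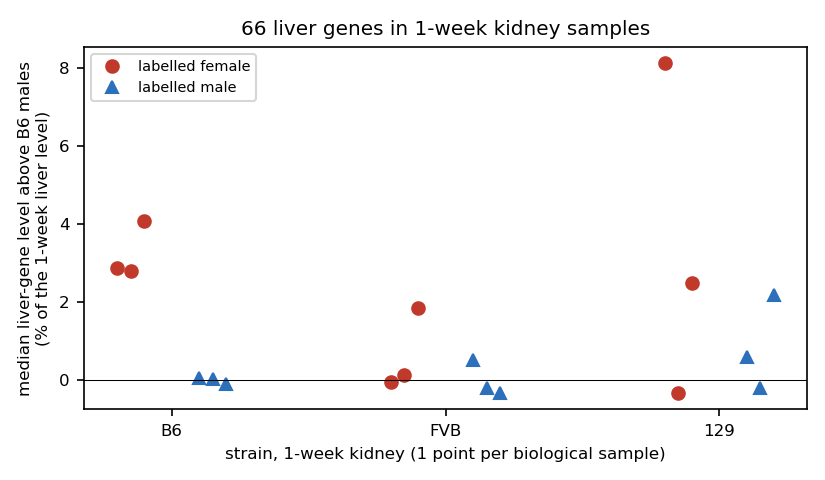
Median excess of 66 liver genes in each 1-week kidney sample over the mean of the B6 kidneys labelled male, as a percentage of their level in 1-week liver. Samples are shown by strain and labelled sex, with 1 point per biological sample. The 3 B6 samples labelled female lie between 2.81% and 4.07% and 129 F1 at 8.11%, and the 3 B6 samples labelled male between -0.0983% and 0.059%.

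Which probes carry a value divides the arrays into 5 sets, and the sets run along the groups. Set A holds 24 samples, all of FVB and replicate 1 of 1-week B6. Set B holds 21 samples, the other 1-week B6 and most of 129 replicates 1 and 2, and set C the other 9 samples of 129. Sets D and E hold 18 samples each, all of 8-week and all of 6-month B6. Tissue differences computed within single sets, correlated across probes, which are not independent replicates, showed 2 parts of the probe numbering. In part 2, liver minus brain correlated at 0.951 between sets A and B and 0.979 between D and E, but at 0.731 to 0.746 between A or B and D or E. In part 1 it correlated at 0.782 between A and B, 0.886 between B and D and 0.885 between D and E, and liver minus kidney at 0.765, 0.792 and 0.868. This structure was found after the values were seen. The strain results and those between 1 and 8 weeks therefore give the count with the array set as a block (A, B, and C to E joined) and the count over matched parts, which are the part and the samples for which the sets gave the most similar tissue differences. Genes described from the matched parts were chosen after their values were seen.

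**Figure D2:**
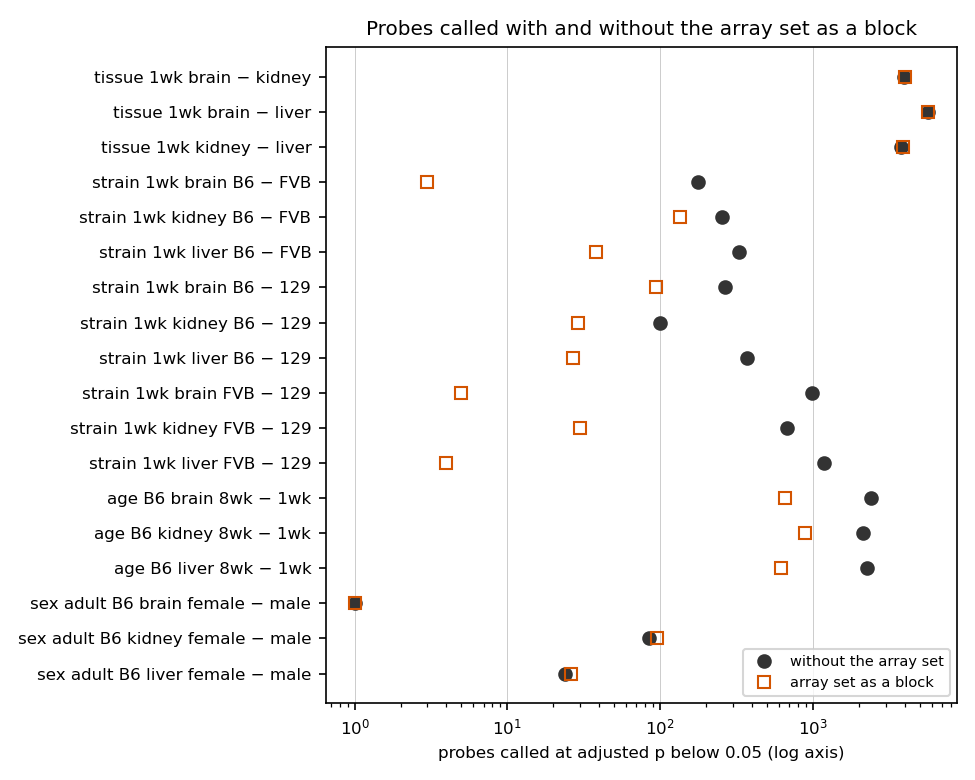
Number of probes called in each comparison, on a log axis, without the array set (filled circles) and with it as a block (open squares). Tissue and adult sex counts lie close together, while FVB minus 129 fell from 989, 673 and 1183 to 5, 30 and 4.

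The strain comparisons set 1-week samples of 2 strains against each other within each tissue, over both sexes. Liver of B6 exceeded liver of FVB for Hc, the complement C5 gene (2.66 ± 0.27, 6.45 ± 0.64, n = 6, against 3.73 ± 0.57, n = 5), and for Igfals, the carrier subunit of circulating growth factor complexes (1.92 ± 0.30). In kidney, the protease inhibitor gene Serpina1c (2.81 ± 0.67) and the mineralisation inhibitor gene Mgp (1.12 ± 0.19) were higher in B6. In brain, the myosin Myo7a (1.35 ± 0.14) and the cell cycle repressor E2f6 (1.33 ± 0.20) were higher in B6 and the G protein subunit Gnb1 lower (-1.46 ± 0.22). Cd74, the invariant chain of class II antigen presentation, was lower in B6 than in FVB in all 3 tissues, by -1.17 ± 0.26 in brain and -1.63 ± 0.30 in liver, as was the acetyltransferase gene Hat1 (-1.03 ± 0.24 in brain, -1.61 ± 0.33 in kidney). Over the matched part, 55, 58 and 110 probes were called in brain, kidney and liver (27 and 28, 21 and 37, 71 and 39 higher and lower in B6), and 6 in all 3 tissues with one sign, against 0.00192 from independent lists. Among leukocyte genes there, H2-Aa was also lower in B6 brain, and Camp and Mpo of granulocytes were lower and C1qc higher in B6 liver. Of the xenobiotic list, the bile acid enzyme Cyp7a1 was higher in B6 liver, as was Afp of the fetal list, and Alad, the haem synthesis enzyme of the strain-variable list, was lower. Liver genes varied between kidney samples as given above, which covers Serpina1c. In male kidneys alone, with 3 samples per strain, 14 probes were called.

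Over all probes, B6 and FVB differed at 177 probes in brain (89 higher in B6, 88 lower), 255 in kidney (178, 77) and 331 in liver (169, 162), with 15 in all 3 tissues against 0.0295 from independent lists. These counts depend on single samples: with 1 sample left out they ran from 31 to 465, 118 to 1365 and 176 to 585. Tissues are not independent here, since they share array sets by replicate number, and with the block 1 of the 15 was called in all 3. With the array set as a block 3, 135 and 38 were called, and within set A 1, 2 and 9 (2 samples of B6 against 6, 6 and 5 of FVB). The naming rule took Erbin, Mrps12, E2f6 and Pigv as higher and Cap1, Csf1, Fbln2 and Myl4 as lower in all 3 tissues, 6 of them in part 1, where these sets differ. In 1 tissue it took 2900019G14Rik, Grin3a, Snap91 and Cap1 in brain, Ccl6, Ttr, Cap1 and Ccl5 in kidney, and Hpd, Hsd17b13, Rbp4 and Cap1 in liver. With the block, the calls left among them were in kidney: Mrps12, Pigv, the chemokine Ccl6 (3.61 ± 0.39 to 3.55 ± 0.55) and transthyretin, Ttr (3.58 ± 0.37 to 3.25 ± 0.51). In brain, Cap1 moved from -2.47 ± 0.54 to -0.07 ± 0.34, so that its difference itself went. Of the 11, 7 and 11 named calls that ended with the block in brain, kidney and liver, 3, 1 and 4 kept at least 0.5 of the fold, with larger standard errors. These were Pigv in brain (0.75 ± 0.14 to 0.90 ± 0.20) and liver (0.94 ± 0.20 to 1.15 ± 0.28), Mrps12 in brain (1.11 ± 0.15 to 0.95 ± 0.22) and liver (1.21 ± 0.20 to 1.13 ± 0.29), E2f6 in all 3 tissues (in brain 1.33 ± 0.20 to 1.04 ± 0.27) and Hpd in liver (3.69 ± 0.56 to 2.71 ± 0.74). The astrocyte list was higher in B6 liver (2 of 10 called, 5 adjusted over the list alone, adjusted p = 0.00942 with an estimated correlation, and 0.23 with the block), with Ndrg2 called over the matched part. In brain the astrocyte list was higher and the cell cycle list lower (adjusted p = 0.703 for both with an estimated correlation), and in liver the cell cycle and ribosomal protein lists were lower (0.173 and 0.279). Hepatocyte genes were higher in B6 liver for 5 of 26 and lower for 1, complement and coagulation genes higher for 4 of 21 and fetal genes for 2 of 10, with adjusted p = 0.0515, 0.0735 and 0.0515 with an estimated correlation. In kidney 3 of 17 tubule genes and 3 of 26 hepatocyte genes were higher in B6 (adjusted p = 0.702 for both with an estimated correlation).

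B6 and 129 differed by several genes in all 3 tissues. Hddc3, a nucleotide hydrolase gene, was lower in B6 by -1.38 ± 0.14 in brain, -1.58 ± 0.26 in kidney and -1.70 ± 0.18 in liver, and was called in each with the block too. Mrps12, a mitochondrial ribosome gene, was higher by 1.66 ± 0.15, 1.10 ± 0.21 and 1.62 ± 0.19. With the block it was called in brain and liver and kept 0.86 ± 0.26 in kidney. Over matched parts the actin regulator Cap1 was lower (-2.09 ± 0.27, -2.51 ± 0.27 and -2.49 ± 0.21). In brain B6 stood at -3.60 for Cap1 in set B and at -0.008 in set A, which the matched part leaves out. Also in brain Myo7a was higher (1.81 ± 0.15, with 129 at -1.33 in set B and -0.223 in set C) and Masp2 (-1.67 ± 0.16) lower. In liver the steroid dehydrogenase Akr1c18 was higher (2.24 ± 0.26) and the P450 Cyp2a12 (-2.38 ± 0.19) and the lipid transporter Abca3 (-2.37 ± 0.23) lower, and Abca3 was lower in kidney too (-1.64 ± 0.31), with Angptl7 (-2.23 ± 0.26). Over matched parts 134, 34 and 40 probes were called (101 and 33, 16 and 18, 24 and 16), 3 in all 3 tissues against 0.000343 from independent lists. Liver rests there on 2 samples of 129 for part 2. Over all probes the counts were 265 (212 higher in B6, 53 lower), 100 (34, 66) and 369 (146, 223), 8 in all 3 tissues against 0.0166 from independent lists, and with the block 94, 29 and 27. With 1 sample left out they ran from 132 to 420, 49 to 228 and 158 to 640. Within set B 22, 6 and 0 were called, the last against 411 at unadjusted p under 0.05 in limma (4 samples against 4, 3 and 2). Of the genes named in 1 tissue, Cd68 and Masp2 were lower in brain and Angptl7 and Cd68 lower in kidney, with the block and over matched parts too. Zbtb14 in brain (1.66 ± 0.37, with the block 0.87 ± 0.27) and in kidney Csf3 (1.29 ± 0.28 to 0.53 ± 0.23) and Klk1 (1.29 ± 0.29 to 0.89 ± 0.39) were higher over all probes and called neither with the block nor over matched parts. There Zbtb14 kept its fold at 1.61 ± 0.42 (adjusted p = 0.0639) and Klk1 most of it at 1.00 ± 0.28 (0.189), while Csf3 fell to 0.51 ± 0.23 (0.719). In liver Itih2 (4.29), Ephx2 (3.66), Ddc (-2.91) and Col1a2 (-2.66) came to 0.005, -0.09, -0.006 and -0.008 with the block. Over matched parts Itih2, Ephx2 and Col1a2 stood at 0.352, 0.14 and 0.143, but Ddc at -2.99 ± 0.75 (adjusted p = 0.103), so the 2 corrections disagree on Ddc. No list was called by camera between B6 and 129 in limma. List members called higher in B6 over matched parts were C1qc, Lyz2, Aqp1 and the growth factor receptor Igf2r in brain, Itih3 in kidney, and Igf2r and Fcer1g in liver. Lower were Masp2, Alad and Cd68 in brain, Pvalb, Eci1, Cel and Cd68 in kidney, and Ces1d and Mcm3 in liver. Itih3, a gene high in liver, stood at 2.43 ± 0.42 in the B6 kidneys labelled female, which carry liver transcripts, and at 0.02 ± 0.21 in those labelled male (SD, n = 3 each). In 129 kidney it stood at -0.222 in set B and 0.83 in set C, and in 129 liver at -0.015 and 5.79, so its call is not read as a strain difference of kidney. Of the 64, 25 and 13 probes of part 2 called over matched parts in brain, kidney and liver, 39, 9 and 4 had 129 samples of set B within 0.5 of the reference level, and 25, 6 and 3 of these kept at least 0.5 of the difference in set C. For genes that did not, the difference rests on the 129 samples of set B. The macrophage gene Cd68 was lower in B6 brain by -2.43 ± 0.16 over the matched part, with 129 at 0.005 ± 0.17 in set B (n = 4) but at -2.31 ± 0.36 in set C (n = 2), near the B6 mean of -2.42. In kidney 129 stood at -0.162 in set B and -1.99 in set C, and in liver at 0.011 and -1.06. Atp2a2 in 129 brain was at 0.05 and 2.06, Ung at -0.016 and -2.83 and Alad at 0.039 and -1.04, against B6 set B means of 1.99, -1.97 and -1.25. Set B levels near 0 are those of the reference RNA, and whether these probes gave signal on the set B slides of 129 is not given in the sources used here. In liver Ctse was at 2.25 in set B and -0.619 in set C. Of the probes of part 2 called over matched parts with a value in set C, 36 of 60, 13 of 19 and 9 of 13 in brain, kidney and liver kept at least 0.5 of the difference there, with C itself unlike A and B in this part. In male kidneys alone, 129 M3 included, 8 probes were called.

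Between FVB and 129, over the matched part, the topoisomerase Top2a was higher (1.66 ± 0.41) and Masp2 lower (-1.63 ± 0.16) in FVB brain. Angptl7 was lower in kidney (-2.21 ± 0.26), and complement Hc was lower in liver (-2.09 ± 0.37, n = 5 against 2). The 1 probe called in all 3 tissues (0.00035 from independent lists), Cd68, and Atp2a2, Pea15a, Ung and the glutathione transferase Gstp3 were called as well, but from 129 levels in set B near 0 that set C does not share. For Gstp3 in liver 129 stood at 0.021 in set B and 3.44 in set C, against 3.23 in FVB, and for Pea15a in brain at 0.092 and 1.25, against 1.82. Of the probes called over the matched part with a value in set C, 22 of 64, 9 of 22 and 8 of 22 in brain, kidney and liver kept at least 0.5 of the difference there. Matched counts were 84, 30 and 22 (47 and 37, 11 and 19, 4 and 18). Without matching, 989 (612 higher in FVB, 377 lower), 673 (246, 427) and 1183 (606, 577) probes were called, 120 in all 3 tissues against 1.85 from independent lists, and 110 of the 120 lay in part 1. With the block 5, 30 and 4 were called and 0 in all 3 tissues. The median standard error rose from 0.174, 0.183 and 0.178 to 0.299, 0.336 and 0.34. Every FVB sample is in set A and no 129 sample is, so no set gives a value of its own for this pair. The genes named for all 3 tissues, Cav1, Ccl5, Csf1, Jchain, Trf, Ube2g1, Ccl6 and Fgd1, all lie in part 1. Among them and the genes named in 1 tissue (Snap91, Cast, 2900019G14Rik, Fgd1, Ccl5, Mycl, Ccl6, Ttr, Rbp4, Itih2, Hsd17b13 and Crym), kidney Ccl6 (-4.24 ± 0.39 to -3.76 ± 0.76) and Ttr (-4.20 ± 0.37 to -3.37 ± 0.71) were called with the block. Hsd17b13 in liver went from -5.41 to -0.44. Of 11, 8 and 12 named calls that ended, kidney Trf (-3.08 ± 0.69 to -1.71 ± 1.37) and liver Ccl5 (2.04 ± 0.23 to 1.40 ± 0.37) alone kept at least 0.5 of the fold. In the unmatched lists 12 of 28 cell cycle genes were higher in FVB brain (17 adjusted over the list alone, adjusted p = 0.661 with an estimated correlation), of which Top2a and Mcm7 were called over the matched part. Astrocyte, hepatocyte and complement lists were lower there (adjusted p = 0.752 for each with an estimated correlation). In kidney 6 of 17 tubule and 4 of 25 hepatocyte genes were lower (adjusted p = 0.513 and 0.669 with an estimated correlation). In liver 4 of 10 astrocyte, 10 of 25 hepatocyte and 8 of 20 complement genes were lower and 3 of 13 ribosomal protein genes higher (adjusted p = 0.0718, 0.0718, 0.384 and 0.384 with an estimated correlation). In male kidneys alone, 129 M3 included, 44 probes were called.

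Age was compared in B6 between 1 week and 8 weeks, over both sexes (n = 6 against 6; 6 against 4 over the matched part, which is part 1 without set A). In liver the cell cycle, matrix and fetal growth lists fell and the male-higher liver list rose by camera with an estimated correlation. The xenobiotic, hepatocyte and complement lists were not called with it. Over the matched part, the major urinary protein Mup9 rose by 5.26 ± 0.23 (0.42 ± 0.32, n = 4, to 5.68 ± 0.57, n = 6), the protease inhibitor Mug2 by 4.63 ± 0.28, the retinal dehydrogenase Aldh1a1 by 4.12 ± 0.29 and complement C9 by 3.46 ± 0.41. Lipoprotein lipase, Lpl (-3.59 ± 0.29), the fatty acid carrier Fabp5 (-3.78 ± 0.26), Igfbp1, which binds insulin-like growth factors (-4.18 ± 0.56), and cyclin Ccna2 (-3.45 ± 0.70) fell. Among genes of part 2, where the sets differ, alpha-fetoprotein, Afp, went from 7.72 ± 0.33 to -0.47 ± 0.21 (n = 6 each), by -8.19 ± 0.38 and with the set block by -8.85 ± 0.72. The lipogenic genes Scd1 (6.59 ± 0.35) and Thrsp (6.56 ± 0.35) and the acute-phase genes Orm1 (6.17 ± 0.18) and Orm2 (5.23 ± 0.17) rose and were called with the block, at 6.56, 6.87, 5.80 and 5.33. The acute-phase gene Crp rose by 5.74 ± 0.50, and by 3.23 ± 0.69 with the block.

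**Figure D3:**
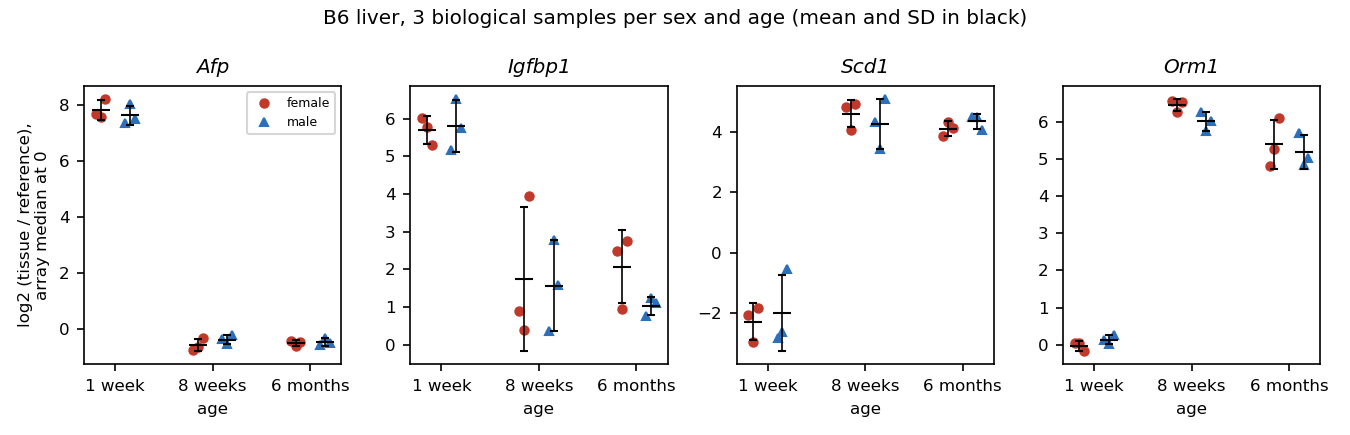
Log2 of tissue over reference for Afp, Igfbp1, Scd1 and Orm1 in B6 liver at 1 week, 8 weeks and 6 months, 1 point per biological sample with the group mean and SD, 6 samples per age. Afp fell from 7.72 at 1 week to -0.47 at 8 weeks, and Igfbp1 fell while Scd1 and Orm1 rose.

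By list, liver cell cycle genes fell for 16 of 28 and rose for 1 (17 fell adjusted over the list alone, median -0.85, adjusted p = 0.0111 with an estimated correlation), with Mcm2 at -2.85 ± 0.29 and Kif20a at -2.48 ± 0.22. Over the matched part 7 of 18 fell, 11 adjusted over the list alone, including the proliferation marker Mki67, the survivin gene Birc5 and the mitotic kinase Cdk1. Matrix genes fell for 13 of 19 (14 adjusted over the list alone, adjusted p = 0.00116 with an estimated correlation), with Sparc at -3.21 ± 0.23 and Nid1 at -2.26 ± 0.15, while Col1a2, of part 2 where the sets differ, rose by 3.69. Over the matched part Lamc1, Fbln2, Nid1, Lum and Eln, 5 of 9, fell. Fetal and imprinted growth genes fell for 5 of 10, among them Igf2 (-2.61 ± 0.32), Cdkn1c (-2.65 ± 0.33) and Gpc3 (-1.40 ± 0.14), and Impact rose (6 fell adjusted over the list alone, adjusted p = 0.0168 with an estimated correlation). All 5 male-higher liver genes rose, including the oxysterol hydroxylase Cyp7b1 (4.81 ± 0.20), Egfr (3.01 ± 0.19) and Elovl3 (2.19 ± 0.21), with adjusted p = 0.0014 with an estimated correlation. Xenobiotic genes rose for 13 of 24 and fell for 2 (Cyp4b1 at -2.98 and Fmo1 at -1.92), with Gstm1 at 2.80 ± 0.21 and Cyp3a11 at 1.05 ± 0.27 (adjusted p = 0.0755 with an estimated correlation). Of 11 in the matched part 6 rose. Leukocyte genes fell for 13 of 23, 14 adjusted over the list alone, among them S100a9 (-3.06 ± 0.28), Ltf (-2.58 ± 0.39) and the microglia and myeloid adaptor Tyrobp (-1.55 ± 0.22), with adjusted p = 0.0564 with an estimated correlation. Hepatocyte genes rose for 8 of 26 (10 adjusted over the list alone), with Plg at 3.96 ± 0.53, while Alb at 1.39 ± 0.79 was not called. The list's adjusted p was 0.215 with an estimated correlation, and its median of 0.46 turned to -0.032 over the matched part. Complement and coagulation genes rose for 7 of 21 and cholesterol synthesis genes for 4 of 8 (adjusted p = 0.449 and 0.25 with an estimated correlation). Adipose genes fell for 3 of 5 and erythroid genes for 2 of 11, and camera called neither list.

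In kidney, the male-higher liver list was the one list called by camera with an estimated correlation between 1 and 8 weeks, where it rose. The epidermal growth factor gene Egf rose by 4.44 ± 0.32 (4.77 with the block) and the organic anion transporters Slc22a6 and Slc22a8 by 3.68 ± 0.22 and 3.29 ± 0.29. Over the matched part the sodium-proton exchanger Slc9a8 rose by 3.74 ± 0.14, Gstm1 by 3.46 ± 0.31 and the kinase Ak4 by 3.76 ± 0.30. Cdkn1c, an imprinted brake on the cell cycle, fell by 3.58 on the log2 scale over the matched part (SE 0.34), Ccna2 by 3.03 (SE 0.72) and the matrix protease Mmp2 by 2.59 (SE 0.33). Tubule genes rose for 12 of 17, 13 adjusted over the list alone, with a median of 1.29 (adjusted p = 0.057 with an estimated correlation). Slc7a9, Slc13a3 and the urate transporter Slc22a12 rose over the matched part, 3 of 9 and 5 adjusted over the list alone. Oxidative phosphorylation genes rose for 12 of 19 and over the matched part for 5 of 11, with the cytochrome oxidase subunits Cox7c at 1.23 ± 0.42 and Cox4i1 at 1.03 ± 0.32 (adjusted p = 0.233 with an estimated correlation). Matrix genes fell for 12 of 19, with Col1a1 at -2.85 ± 0.22 and Sparc at -2.21 ± 0.17, and fetal genes for 4 of 10, with Gpc3 at -1.58 ± 0.20, each with adjusted p = 0.057 with an estimated correlation. Cell cycle genes fell for 14 of 28, with Mki67 at -1.38 ± 0.26 (adjusted p = 0.233 with an estimated correlation). The male-higher liver list rose for 4 of 5 genes, 5 adjusted over the list alone, with Cyp2d9 at 4.43 ± 0.33 and Cyp7b1 at 2.70 ± 0.23 (adjusted p = 0.0172 with an estimated correlation). The male-higher kidney list rose for 5 of 8, with Hsd11b1 at 3.34 ± 0.19 and the polyamine enzyme Odc1 at 2.63 ± 0.38, and was not called by camera. The neuron list fell for 5 of 16 and the strain-variable list rose for 3 of 7 (adjusted p = 0.233 and 0.275 with an estimated correlation). Afp fell by 5.38 on the log2 scale (SE 0.51) and by 4.19 in males alone, beside the liver transcripts in the 1-week female kidneys. Of the other genes named in kidney, Dusp2, Gclc, Slc6a19, 5930403L14Rik, Itgb2, Sgk2, Cpox and Scd1 rose and Mthfd2, Apcdd1 and Ung fell with the block too, while Pth1r, Fos, Pabpc2, Dpp4, Tnfrsf10b and Tgtp1 were not called with it.

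In brain, Clu, a secreted chaperone of astrocytes, rose over the matched part by 1.94 ± 0.32, the Polycomb gene Cbx7 by 2.06 ± 0.24 and Gstm1 by 1.72 ± 0.27. The transcription factors Sox12 (-2.75 ± 0.26) and Tead2 (-2.24 ± 0.19), nuclear lamin Lmnb1 (-2.51 ± 0.33) and Ccna2 (-2.44 ± 0.54) fell. Myelin genes rose for 6 of 9 and fell for 1, with Sox10 at 2.34 ± 0.28, myelin-associated Mag at 1.23 ± 0.29 and Olig2 at -2.89 (adjusted p = 0.415 with an estimated correlation), and Mag rose over the matched part. Mbp stood at -1.15 ± 0.60 and was not called. Astrocyte genes rose for 4 of 10, including S100b (1.70 ± 0.33) and Sparcl1 (1.39 ± 0.26), and Fabp7 of radial glia fell by 2.44 (SE 0.27). Cell cycle genes fell for 12 of 28 and rose for 4, with Rrm2 at -1.95 ± 0.24, and matrix genes fell for 5 of 19 (adjusted p = 0.415 for both with an estimated correlation). Over the matched part 6 of 18 cell cycle genes and the matrix genes Fbln2 and Nid1 fell. Neuron genes rose for 4 of 16 and fell for 3, among them Dcx at -2.27 ± 0.40, and cholesterol synthesis genes fell for 4 of 8; camera called neither list nor the astrocyte list. Of the 20 genes named, Pcsk1n, Plekhb1 and Nat8l rose by 5.08 ± 0.54, 4.87 ± 0.33 and 4.49 ± 0.33 (1.24, 2.81 and 2.43 with the block), Ctse rose by 4.07 ± 0.35 and the differentiation antigen Cd24a fell by 4.14 (SE 0.40). The other 15, Chgb, Stmn4, Nap1l2, Cd74, Nell2, Pkia, Stmn3, Fos, Etv4, Aplp1, Snai1, Pabpc2, Efr3b, Sfrp2 and Mthfd2, were not called with the block. Efr3b alone kept at least 0.5 of the fold (-3.45 ± 0.72 to -1.83 ± 1.33).

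Between 1 and 8 weeks limma called 2387 of 10382 probes in brain (1236 rose, 1151 fell), 2122 in kidney (1287, 835) and 2262 in liver (980, 1282). With the block it called 656, 894 and 615, of which 375, 670 and 476 had been called with one sign without it. Male kidneys alone gave 1419 (831, 588). Over the matched part, of 5409 probes, 532 (152, 380), 762 (538, 224) and 537 (309, 228) were called. Age and array set coincide in B6, so the block rests on 129 samples of set C standing for D and E, unlike them in part 2. In part 1, liver minus brain and liver minus kidney correlated at 0.886 and 0.792 between matched sets B and D. Sets D and E gave 0.885 and 0.868 there, and A and B 0.951 and 0.952 in part 2. So the matching is weak and leaves the set open. Also called with the block in liver were Mug2, Ap4s1, Apof and Cyp7b1, which rose, and P4ha1, Tgtp1, Nrap and Pth1r, which fell. Itih2 (-6.25 to 0.001), Ephx2, Pabpc2 and Gli2 were not.

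From 8 weeks to 6 months, where each age is an array set of its own, the sets gave like tissue differences in part 2, and there the changes were few in brain and kidney and more in liver (n = 6 against 6). In liver, complement and coagulation genes Mbl1, Hc and F2 fell, 3 of 14 (5 adjusted over the list alone), as did Egfr of the male-higher liver list and Afm, a vitamin E binding protein (-1.43 ± 0.21). Pdgfa (1.46 ± 0.17), the Wnt modulator Sfrp2 (1.43 ± 0.21), the mitochondrial nucleotide carrier Slc25a4 (3.02 ± 0.49) and Ska1 of the mitotic spindle (1.78 ± 0.30) rose. In kidney Ucp1 of brown fat fell (-2.18 ± 0.45), as did Akr1c18 (-1.09 ± 0.19) and the stress gene Ndrg1 (-1.33 ± 0.27), and Pdgfa rose (0.94 ± 0.20). In brain the receptor Gabbr1 (-2.04 ± 0.27) and the connexin Gjb6 of astrocytes (-1.71 ± 0.24) fell, and Camk2d (1.20 ± 0.20) and Ptk7 (1.47 ± 0.30) rose. In part 2, 9, 15 and 330 of 5299 probes were called in brain, kidney and liver (3 and 6, 7 and 8, 256 and 74). Over both parts the counts were 551 (264 rose, 287 fell), 431 (168, 263) and 1021 (479, 542), with 508, 376 and 738 of them in part 1. The block joins sets D and E, so it cannot move folds here or for adult sex, and gave 640, 496 and 1147. All 18 genes named by the rule lie in part 1, where the tissue differences of the sets are less alike: Slc22a17, Ina, Slc4a10, Acta2, Efnb3 and Sdc1 in brain, Dao, Abhd14b, Elavl4, Polg, Slc12a1 and Slc4a4 in kidney, Rbp4, C8g, Gpt, Acta2, Polg and Crot in liver. Slc22a17 went from 0.09 to 4.87 and Rbp4 from 0.23 to 6.02. No list was called by camera. Male kidneys alone, a contrast without 1-week samples, gave 221 probes.

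The sex comparison at 1 week set female against male samples over the 3 strains. No probe passed in brain, kidney or liver in limma, against 272, 259 and 1305 at unadjusted p under 0.05, where chance alone gives 563, 487 and 487. In brain Xist, which coats the inactive X, was higher in females by 0.36 ± 0.15 and the X-linked demethylase Kdm6a by 0.37, and the Y-linked Kdm5d and Eif2s3y were lower by -0.29 and -0.32; all passed when adjusted over the list alone. In kidney the hepatocyte list was higher in females by camera, with 0 genes called and 7 adjusted over the list alone, among them Alb (2.03 ± 0.52), Apoa1 (1.48 ± 0.53) and Hpx (1.11 ± 0.35), beside the liver transcripts of those samples (adjusted p = 0.0559 with an estimated correlation). The complement list stood likewise, with Hc at 0.69 ± 0.15 (0 called, 4 adjusted over the list alone, adjusted p = 0.0824 with an estimated correlation). The fatty acid oxidation, xenobiotic and oxidative phosphorylation lists were called by camera with 0 members called (adjusted p = 0.397, 0.397 and 0.694 with an estimated correlation). A score of Xist minus the mean of Kdm5d and Eif2s3y was higher in female than male samples by 1.06 in FVB (exact permutation p = 0.00025 within tissue, adjusted p = 0.000417, n = 8 and 9) and 0.774 in 129 (exact p = 0.00275, adjusted p = 0.00344, n = 9 and 9). These p-values take the tissues of one replicate number as separate samples. In 1-week B6 it was lower in samples labelled female, by -0.634 (exact p = 0.053, adjusted p = 0.053, n = 9 and 9), in all 3 tissues and in 8 of 9 pairs of one replicate number. If a number is 1 animal there are 3 per sex and 20 arrangements, so p cannot fall below 0.1, and with tissues averaged per number it was 0.1 in FVB and in 129 and 0.2 in 1-week B6. With FVB and 129 alone 1, 0 and 187 probes were called in brain, kidney and liver. Within sets A, B and C no probe was called in limma except 9 in kidney in set C, where 1 female stood against 2 males; at unadjusted p under 0.05 the sets gave 59 to 958.

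**Figure D4:**
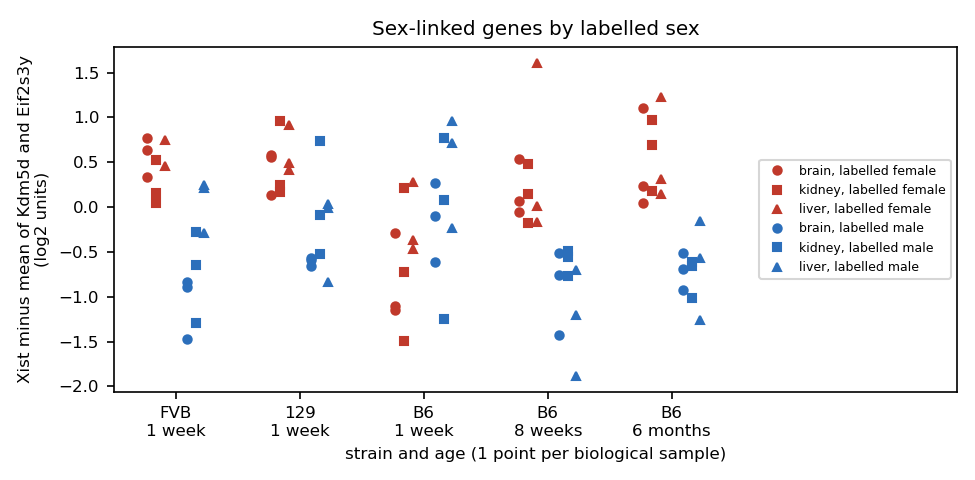
Xist minus the mean of Kdm5d and Eif2s3y, on the log2 scale, for each biological sample by strain, age and tissue, with samples labelled female in red and male in blue. Female means lie above male in 12 of 12 group pairs outside 1-week B6 and below in the 3 pairs of 1-week B6.

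In adult B6 (8 weeks and 6 months, n = 6 against 6), kidney showed the clearest sex difference. Akr1c18, a progesterone-metabolising enzyme, was higher in females by 2.42 ± 0.21 (3.85 ± 0.54 against 1.43 ± 0.83) and the carbonyl reductase Cbr1 by 2.36 ± 0.14 (2.46 ± 0.16 against 0.10 ± 0.32). Cyp7b1 was lower in female kidney by -3.25 ± 0.23 (1.89 ± 0.36 against 5.14 ± 0.61), the methyltransferase Inmt by -2.37 ± 0.22 and the protease inhibitor Pzp by -2.18 ± 0.40. In liver the steroid hydroxylase Cyp17a1 was higher in females by 1.96 ± 0.18 (3.07 ± 0.36 against 1.11 ± 0.22) and the metallothioneins Mt1 and Mt2 by 1.70 ± 0.22 and 1.67 ± 0.28. Lower were Gstp1 (-2.87 ± 0.28, 0.19 ± 0.52 against 3.06 ± 0.65), Elovl3 (-2.54 ± 0.21) and Cyp7b1 (-2.26 ± 0.20). Also higher in females were Rdh16f2, Cyp4a14, Bhmt, Kcnk1, the immunoproteasome subunit Psmb8 and Scd1 in kidney, by 1.68 to 2.36, and Cyp2c69, Ccnd1, Rdh16f2, Zic1 and Psmb8 in liver, by 1.35 to 2.39. Lower were Cyp2d9, Galns, Serpinf2, the transporter Slc22a30 and Odc1 in kidney, by -1.94 to -1.56, and Terf1, Mcm10 and Selenbp1 in liver, by -1.59 to -1.31.

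**Figure D5:**
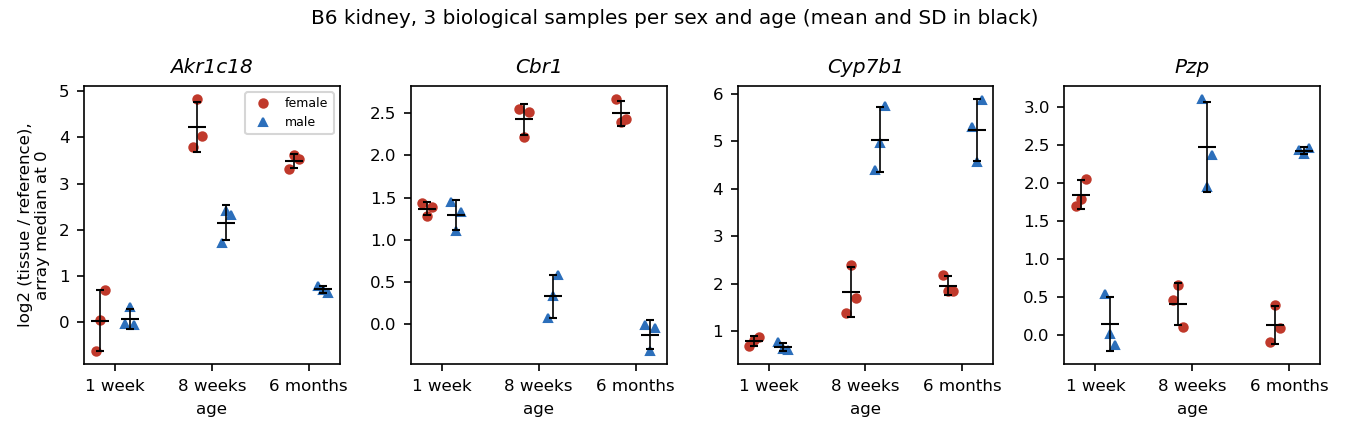
Log2 of tissue over reference for Akr1c18, Cbr1, Cyp7b1 and Pzp in B6 kidney at 1 week, 8 weeks and 6 months by labelled sex, 1 point per biological sample with the group mean and SD, 3 samples per sex and age. In adults, Akr1c18 and Cbr1 were higher and Cyp7b1 and Pzp lower in females.

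Of the lists of genes known to differ between the sexes, camera with an estimated correlation called the male-higher liver list in liver and kidney, the female-higher liver list in liver and the Xist list in brain. In liver 3 of 5 male-higher genes were lower in females, 5 adjusted over the list alone, with a median of -2.26 (adjusted p = 2.71e-07 with an estimated correlation). Of 6 female-higher liver genes Cyp17a1 was higher, with Cyp39a1 (0.59 ± 0.20) passing when adjusted over the list alone (adjusted p = 0.00146 with an estimated correlation). In kidney the male-higher liver list was lower in females for Cyp7b1 and Cyp2d9, 2 of 5 (3 adjusted over the list alone, adjusted p = 0.000607 with an estimated correlation). The male-higher kidney list was lower for Slc22a30 (-1.70 ± 0.25) and Odc1 (-1.56 ± 0.38), 2 of 8 (4 adjusted over the list alone, adjusted p = 0.058 with an estimated correlation), while Kap, the androgen-regulated protein, stood at 0.52 ± 0.76 and was not called. Both measured female-higher kidney genes, Cyp4a14 (2.03 ± 0.36) and the transporter Abcc3 (0.81 ± 0.19), were higher in females; with 2 members this list and the Y-linked list were not tested as lists. Xist was higher in female liver by 1.07 ± 0.24 and brain by 0.63 ± 0.18, and Kdm5d lower by -0.54 ± 0.15 in liver, -0.60 ± 0.15 in kidney and -0.69 ± 0.13 in brain, each passing when adjusted over the list alone. The list of Xist and X-linked genes that escape inactivation was higher in female brain (adjusted p = 0.0117 with an estimated correlation) and liver (0.131). Adipose, astrocyte, myelin, adrenal and matrix lists were higher in female kidney by camera (adjusted p = 0.058, 0.0744, 0.0915, 0.213 and 0.556 with an estimated correlation), leukocyte genes in liver (0.524) and hepatocyte and complement genes in brain (0.536 and 0.517). In limma 85 probes were called in kidney (52 higher in females, 33 lower), 24 in liver (16, 8) and 1 in brain, lower and without a gene symbol. The block, which cannot move these folds, gave 95, 26 and 1. Within single ages the counts were 32 and 14 in kidney, 1 and 1 in liver and 0 and 0 in brain (808 and 63 at unadjusted p under 0.05), with the sign of the pooled fold at all 85 and 24.

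The last comparison asked whether the sex difference itself differed between adult and 1-week B6. It did in kidney for Akr1c18 (2.46 ± 0.36) and Cbr1 (2.29 ± 0.25), which were more female-high in adults, and for Pzp (-3.89 ± 0.69) and Cyp7b1 (-3.38 ± 0.40), more male-high in adults. Pzp is among the genes highest in liver, and the 1-week kidneys labelled female, which carry liver transcripts, stood at 1.69 to 2.05 for it, against -0.141 to 0.536 in those labelled male. Its adult difference alone was -2.18. In liver it did for Cyp17a1 (2.24 ± 0.30), Zic1 (1.58 ± 0.25), Gstp1 (-2.82 ± 0.48) and Elovl3 (-2.57 ± 0.37). In limma 12 probes were called in kidney (5 up, 7 down), 7 in liver (3, 4) and 1 in brain without a gene symbol. The male-higher liver list differed in liver, with 3 of 5 genes down (adjusted p = 7.55e-07 with an estimated correlation), and in kidney, with 1 down (0.00144), as did the female-higher liver list in liver, with 1 up (0.00274), and the Xist list in liver (0.0408). The hepatocyte, complement, xenobiotic, oxidative phosphorylation and male-higher kidney lists were down in kidney by camera, with at most 1 member called in each (adjusted p = 0.071, 0.0806, 0.0823, 0.333 and 0.0747 with an estimated correlation), beside the liver transcripts in 1-week female kidneys. This contrast takes the 1-week B6 labels as given; with 1-week FVB and 129 in their place 0, 32 and 93 probes were called in brain, kidney and liver, and the 8 named genes were called there too.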

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

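The tests of the array set and of strain, of the sex-linked score and the unnamed probe, of 1-week FVB and 129 in place of B6 and of a sex difference of 1-week kidneys were chosen after the results were seen, while the contrast of sex by age and the test of liver RNA in kidney samples were planned. The sex difference differed between adult and 1-week B6, by a test of the difference itself, at 1 probe in brain, 12 in kidney and 7 in liver. In kidney these included Akr1c18 (2.46 ± 0.36), Cbr1 (2.29 ± 0.25), Pzp (-3.89 ± 0.69) and Cyp7b1 (-3.38 ± 0.40). Part of the value for Pzp comes from the 1-week kidneys labelled female that carry liver transcripts, and the adult difference alone was -2.18. In liver they included Cyp17a1 (2.24 ± 0.30), Zic1 (1.58 ± 0.25), Gstp1 (-2.82 ± 0.48) and Elovl3 (-2.57 ± 0.37), with 6 adult and 3 1-week samples of each sex. With 1-week FVB and 129 in place of 1-week B6 these 8 genes were called too. The score of Xist minus the mean of Kdm5d and Eif2s3y also differed, by 1.86 between the adult and the 1-week sex difference (permutation p = 1e-04, the smallest that 10000 permutations can give, with tissues taken as separate samples; exact p = 0.00225 over 8000 arrangements with each replicate number taken as 1 animal).

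Between FVB and 129, 120 probes were called with one sign in all 3 tissues. The array set is a candidate cause: at 93.06% of their values the difference between sets A and B within B6 had the sign of FVB minus 129, against 61.5%, 38.4% and 60.5% of all tested probes in brain, kidney and liver. With the set as a block the median ratio of the fold with the block to that without was 0.288, 2, 1 and 0 of the probes were called, and the median fold went from 1.23, 1.095 and 1.06 to 0.41, 0.42 and 0.22 while the median standard error rose from 0.234, 0.236 and 0.243 to 0.341, 0.393 and 0.363, so the calls ended with smaller folds and larger errors alike. A strain difference stays open for what is left, since strain and set are separated only through B6, with 2 samples per tissue in set A. From 8 weeks to 6 months the share of probes called was at least 2.77 times as high in part 1, where the tissue differences of the sets correlated at 0.885 and 0.868, as in part 2, where they did at 0.979 and 0.965, which is consistent with the array set as a source of calls in part 1. There age and set cannot be told apart, since each age is a set of its own.

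Sex-linked genes ran against the labels in 1-week B6, with a mean score difference, female minus male as labelled, of -0.634 (exact permutation p = 0.053 within tissue, 8000 arrangements, adjusted p = 0.053, 8 of 9 pairs of one number). Probes that do not read sex are argued against, since in 12 of 12 other group pairs the female mean was higher, by 0.415 to 1.75. An unnamed probe was found as lower in females in adult B6 (-1.16 and -1.45). It was lower in FVB and 129 too (-0.425 and -0.825, exact permutation p = 0.0205 and 0.00225). It was higher by 0.261 in 1-week B6 as labelled (exact p = 0.048). These p-values take tissues of one number as separate samples, although in 14 of 30 tissue pairs all 3 numbers correlated above 0.1. With a number as 1 animal no p within a group can fall below 0.1, and score and probe gave 0.2 in 1-week B6. An exchange of sex labels among 1-week B6 samples may explain this and stays open, because the p misses 0.05 and 1 pair of one number runs the other way. No biological explanation was tested.

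In 7 of 18 1-week kidneys, among them all 3 B6 samples labelled female, genes of liver reached a median of 1.87% to 8.11% of the liver level, against at most 0.596% in the others. Of 44 genes outside the hepatocyte and complement lists that were at least 8-fold higher in liver than in kidney, 97.73% were higher in the B6 kidneys labelled female than in those labelled male, against 59.1% of kidney-high and 25% of brain-high genes. Liver RNA in samples labelled kidney may explain this, as the excess in the female-labelled B6 kidneys followed the level in liver across 66 genes (Spearman 0.734, Pearson 0.652; genes are not independent replicates), and the most abundant genes rose together, Alb to 4.39 against 0.22, Apoa1 to 2.93 against 0.22 and Bhmt to 2.71 against 0.12. A sex difference of 1-week kidneys as the whole cause is argued against, since 4 of 9 male kidneys lay above at least 1 female kidney of their strain. A difference between single samples in kidney expression of these genes stays open.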

How the results depend on the processing

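Alternatives marked as added were chosen after seeing the data; the cause of a change was not tested unless stated. No alternative reversed the sign of a tissue marker, an adult sex gene or a named sex by age gene. Planned centring of arrays gives no value of its own, since the values used are centred. Signal over background is not given in the sources used here, so what it limits was not tested; the number of arrays and samples limits the precision.

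With Cy3 arrays only, which leaves fewer arrays, limma called 3747 probes for brain minus liver and 2441 for kidney minus liver, 709 and 519 for B6 minus FVB in kidney and liver, 53 and 157 for B6 minus 129 in brain and liver, and 427 for FVB minus 129 in liver. It called 3662 and 1456 for 8 weeks minus 1 week and 1594 and 516 for 6 months minus 8 weeks in brain and liver, 0, 41 and 13 for adult sex in brain, kidney and liver, 0 and 3 for sex by age in brain and liver, and 5 and 54 common to 3 tissues for B6 and FVB minus 129. With Cy5 arrays only the counts were 29 and 67 for B6 minus FVB in brain and kidney, 88, 50 and 63 for B6 minus 129, and 512 and 559 for FVB minus 129 in brain and liver. They were 4381 for 8 weeks minus 1 week in brain, 2518 and 415 for 6 months minus 8 weeks in brain and liver, 40 and 12 for adult sex in kidney and liver, 0, 3 and 1 for sex by age, and 6, 1 and 40 common to 3 tissues. There the median of the female-higher liver list in sex by age in liver reversed to -0.008.

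Scaling of arrays to one spread gave 60, 91 and 76 for B6 minus FVB, 127 and 66 for B6 minus 129 in brain and kidney, and 7 common for B6 minus FVB (5 higher, 2 lower). The array-level fit with a dye term, which counts arrays, gave 608, 585 and 964 for B6 minus FVB, 721, 346 and 930 for B6 minus 129, and 1024 and 1987 for FVB minus 129 in kidney and liver. It gave 739 for 6 months minus 8 weeks in kidney, 19 for sex at 1 week in kidney, 2, 134 and 79 for adult sex, 48 and 17 for sex by age in kidney and liver, and 119, 52 and 252 common. With only the groups of the contrast in the fit, which leaves fewer degrees of freedom, the counts were 14, 29 and 104 for B6 minus FVB, 18, 13 and 35 for B6 minus 129, 135 for adult sex in kidney, 0, 27 and 4 for sex by age, and 2 and 1 common for B6 minus FVB and B6 minus 129. Including the arrays with contradictory labels gave 23 common for B6 minus FVB, and the replicate number as a block gave 570 for B6 minus 129 in liver. Without the probe filter no count left the range of 1.5 times.

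The array set as a block (added) gave 3, 135 and 38 for B6 minus FVB, 94, 29 and 27 for B6 minus 129, 5, 30 and 4 for FVB minus 129, 656, 894 and 615 for 8 weeks minus 1 week, 1 for sex at 1 week in kidney, and 1, 4 and 0 common. Of the probes called without it, 3, 39 and 25 for B6 minus FVB, 82, 23 and 21 for B6 minus 129, 4, 12 and 1 for FVB minus 129 and 375, 670 and 476 for 8 weeks minus 1 week were called with one sign in both. The median standard error rose from 0.172 to 0.298, 0.184 to 0.321 and 0.168 to 0.302 between 1 and 8 weeks, and the median ratio of the folds of called probes with the block to those without was 0.715, 0.866 and 0.842. The block reversed 25 named values, none of them called with the block: for B6 minus FVB Cap1 in kidney (0.159) and liver (0.052), Myl4 in liver (0.094), 2900019G14Rik (-0.314) and Snap91 (0.128) in brain, Hsd17b13 (-0.036) and Rbp4 (0.43) in liver, and for B6 minus 129 Ephx2 in liver (-0.09). For FVB minus 129 it reversed Cav1 in kidney (-0.449) and liver (-0.47), Trf in brain (0.257), Ube2g1 (0.586) and Ccl6 (0.156) in liver, Fgd1 in brain (0.759) and liver (0.719), Snap91 in brain (-0.071), Mycl in kidney (-0.02) and Rbp4 (-0.624), Itih2 (-0.76) and Crym (0.553) in liver. Between 1 and 8 weeks it reversed Aplp1 (0.04) and Pabpc2 (0.15) in brain, Pth1r (0.498) and Dpp4 (1.03) in kidney and Itih2 in liver (0.001).

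Matched slide parts (added), which test fewer probes and samples, gave 55, 58 and 110 for B6 minus FVB, 134, 34 and 40 for B6 minus 129, 84, 30 and 22 for FVB minus 129, 532, 762 and 537 for 8 weeks minus 1 week, 9, 15 and 330 for 6 months minus 8 weeks, and 6, 3 and 1 common. It reversed Col1a2 in liver for B6 minus 129 (0.143) and the hepatocyte list in liver between 1 and 8 weeks (-0.032). Without centring (added) the counts were 119 and 38 for B6 minus 129 in brain and kidney, 646 for 6 months minus 8 weeks in liver and 27 common for B6 minus FVB. It moved the median of all probes by over 0.1 for B6 minus FVB in liver (-0.01 to 0.16), FVB minus 129 in brain (0.04 to -0.09) and liver (-0.003 to -0.22), 8 weeks minus 1 week in brain (-0.02 to 0.13) and kidney (0.04 to -0.09), sex at 1 week in brain (0.01 to -0.11) and kidney (-0.02 to -0.14), adult sex in kidney (-0.01 to 0.15) and sex by age in kidney (0.03 to 0.30). Splits of higher and lower moved with it, to 116 and 44, 190 and 29, and 354 and 50 for B6 minus FVB, 299 and 585 in brain and 215 and 1165 in liver for FVB minus 129, 1725 and 600 in brain and 860 and 970 in kidney for 8 weeks minus 1 week, and 70 and 19 for adult sex in kidney. Male kidneys alone (added) gave 14, 8 and 44 for the 3 strain pairs and 221 for 6 months minus 8 weeks. Without 1-week B6 (added) sex at 1 week gave 1 in brain and 187 in liver, and 1-week FVB and 129 in place of 1-week B6 (added) gave 0, 32 and 93 for sex by age.

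Leaving out each sample in turn gave 31 to 465, 118 to 1365 and 176 to 585 for B6 minus FVB in brain, kidney and liver, 132 to 420, 49 to 228 and 158 to 640 for B6 minus 129, and 767 to 1046, 417 to 743 and 678 to 1201 for FVB minus 129. It gave 3823 to 4208, 5315 to 5755 and 3545 to 4258 for the tissue pairs, 1963 to 2265, 1828 to 2285 and 1931 to 2327 for 8 weeks minus 1 week, 425 to 645, 320 to 517 and 687 to 1019 for 6 months minus 8 weeks, and 0 to 0, 0 to 14 and 0 to 165 for sex at 1 week. For adult sex it gave 1 to 2, 66 to 79 and 17 to 35, for sex by age 0 to 2, 5 to 16 and 7 to 8, and for calls common to 3 tissues 10 to 29, 6 to 11 and 74 to 124. The count left the range of 1.5 times for 10, 6 and 6 of the 12, 12 and 11 samples of B6 minus FVB, for 5, 6 and 7 of 12 of B6 minus 129, and for 0, 3 and 2 of FVB minus 129. For B6 minus FVB the lowest and highest values came without B6 M3 and B6 M1 in brain, FVB M1 and B6 F3 in kidney, and B6 M3 and B6 F1 in liver. For B6 minus 129 they came without B6 F1 and B6 F2, 129 F3 and 129 M1, and 129 M3 and 129 F1. For FVB minus 129 the lowest came without FVB M1 in kidney and FVB F1 in liver. Sex at 1 week reached 14 in kidney without 129 F2 and 165 in liver without FVB F1, against 0 in limma with 272, 259 and 1305 probes at an unadjusted p under 0.05 in brain, kidney and liver. Sex by age gave 0 in brain without B6 1-week F3 and 2 without B6 1-week M1, and in kidney 5 without B6 1-week F2. Adult sex gave 2 in brain without 6-month F1. Calls common to 3 tissues gave 29 for B6 minus FVB without B6 liver F1, 10 without B6 brain F2, and 74 for FVB minus 129 without FVB liver F1. A group left with 1 sample is assumed to vary like the others.

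Of 259 values of named genes, the block lost the call of 68 and reversed 25. Calls were lost for 24 with scaling, 26 with Cy3 and 33 with Cy5 arrays, 46 with only the groups of the contrast, 22 of 93 in males alone, 9 of 27 over matched parts and 0 with the array-level fit, no filter or copied values left out. Of 4531 values with 1 sample left out 153 lost the call and 0 reversed. Of 52 list medians followed, 7 moved with the block, 9 with Cy3 and 10 with Cy5 arrays. With an estimated correlation 25 of 52 lists called by camera were no longer called.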

Other observations

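Other splits, correlations of single arrays, shared values and second probes were examined after seeing the results, while the real counts come from planned comparisons. Per comparison, 100 splits of its samples into groups of the same sizes were drawn, the real one included. Chance is excluded if only the real split called as many (1 of 100). This held for brain minus kidney, brain minus liver and kidney minus liver (3953, 5670 and 3779 probes against at most 1489, 3598 and 1754). It held for 8 weeks minus 1 week in brain, kidney and liver (2387, 2122 and 2262 against 628, 1210 and 1124). So it did for 6 months minus 8 weeks (551, 431 and 1021 against 91, 206 and 48). Ages part along the array sets, so this does not exclude the set. For sex at 1 week chance is not excluded, since limma called 0 and all 100 splits as many or more (highest 76, 1914 and 1554; 272, 259 and 1305 probes at an unadjusted p under 0.05). For adult sex it is not excluded in kidney (85 against 110, 3 of 100) or brain (1 against 50, 28 of 100). Nor is it in liver (24 against 202, 18 of 100). For sex by age it is not excluded in brain (1 against 65, 22 of 100), kidney (12 against 389, 8 of 100) or liver (7 against 100, 14 of 100). This holds for the number of probes called and not for each gene. The smallest adjusted p was 1.61e-12 for adult sex in liver, and 1.49e-05 and 7.29e-07 for sex by age in kidney and liver. The male-higher liver list, fixed beforehand, was called in liver in both (adjusted p = 2.71e-07 and 7.55e-07 with an estimated correlation), which argues against chance for these genes. Splits that call several times the real count, as in sex at 1 week, adult sex in brain and liver and sex by age, point to a structure of the samples other than sex.

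Chance is excluded for strain counts except B6 pairs in kidney and B6 minus FVB in liver, where other splits called more. The splits do not exclude the array set, along which FVB and 129 part. B6 minus FVB gave 177, 255 and 331 against 157, 1303 and 535 (1, 4 and 2 of 100). B6 minus 129 gave 265, 100 and 369 against 113, 730 and 337 (1, 3 and 1 of 100). FVB minus 129 gave 989, 673 and 1183 against 192, 135 and 677 (1 of 100 in each). For calls common to 3 tissues the values were 15 against 4, 8 against 1 and 120 against 0 (1 of 100 in each). The highest other split of B6 minus FVB in liver, with 535, set 6 samples of set A against 1 of A and 4 of B, and so followed the array set. In kidney the highest other splits put 4 of A and 2 of B on both sides for B6 minus FVB (1303), and 1, 4 and 1 of A, B and C against 1, 3 and 2 for B6 minus 129 (730). These do not follow the set and point to another structure of the kidney samples.

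Under a 129 brain title, 3 arrays, 1 of sample M2 and 2 of F3, name liver as the source of the tissue channel, and belong to no group. They correlated across probes at 0.814, 0.762 and 0.69 with the brain mean and at 0.2, 0.27 and 0.257 with the liver mean. Of the 3 arrays whose lines state different dyes, FVB liver F2 and M2 correlated with the liver mean at 0.742 and 0.829, and B6 liver M1 at -0.845. Genes and probes are not independent replicates in these correlations.

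An array of B6 1-week liver F3 and one of M3 shared 3623 identical values, 30.47% of their probes. Pairs of arrays within a sample shared 6414 (57.06%, FVB liver F2), 4655 (39.03%, 129 kidney F2) and 5779 (48.76%, 129 brain M2). Where a called gene had further probes, these had its sign for 77.74%, 71.65% and 69.02% of probes in the tissue pairs, 68.75%, 69.84% and 65.71% for 8 weeks minus 1 week in brain, kidney and liver, and 27.78% to 70% in the strain comparisons.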
